A study of Sus scrofa with 12 samples.

How the data were processed

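Small RNA was sequenced from the small intestine of Large White pigs ("Big white" in the labels) in 12 libraries. The labels place 3 libraries in each of 4 groups: piglets still feeding from the sow after 21 days of age, and piglets weaned for 1, 3 or 7 days after that age. The labels do not say whether each library came from a different animal, which part of the small intestine was taken, or the sex and litter of the piglets, so p-values measure the spread between libraries. As the labels read, weaning followed 21 days of age, so among the weaned groups age goes with days of weaning. The age of the feeding piglets on the day of sampling is not given, so against feeding days of weaning may go with age too.

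The deposited table holds, for each library, a list of small RNA identifiers with a count and a TPM value, per the file headers. The counts are whole numbers, and a small RNA not seen in a library is missing from its list, so it was entered as 0. The deposited TPM equals the CPM (counts scaled by the library total) of the library's own list, with no length term, within 0.005. Genome build Sscrofa 11.1 is named per the submitters' processing notes. The aligner, the counting tool, their versions, and the rule for a read that matches several names are not given in the sources used here. Totals ran from 24670093 to 27784417 counts per library. Each list also holds 3 totals for reads in exons, introns and intergenic sequence, which took 19.96% to 62.17% of a library. These totals name no small RNA and were left out of the tests, which leaves 10453953 to 21031457 counts per library. The named identifiers comprise 337 known microRNAs, 1342 predicted microRNAs, 3433 predicted piRNAs and 738 Rfam families. The counts of 8 microRNA names that a list gives more than 1 time were summed. Reads from microRNAs of near-identical sequence, such as miR-194a with miR-194b or miR-199a with miR-199b, can be split between names in a way the sources do not describe, so single values of such names are uncertain. PCR copies are not told apart, so intervals cover counting error only.

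The test planned before the data were examined was limma on log2 values, with edgeR if the files held raw counts. The files held counts, so edgeR 4.0.16 was used (R 4.3.3). Small RNAs were kept by filterByExpr (a minimum count of 10 and a minimum total of 15), which left 2453, of which 295 were known microRNAs. TMM factors, a fit of 4 group means over all 12 libraries, and the quasi-likelihood test were used, two-sided. Each of the 6 contrasts and the test among the 4 groups had its own Benjamini-Hochberg adjustment, with a threshold of 0.05. Levels are normalised CPM with TMM factors, as mean ± SD over 3 libraries, and log2 fold changes carry their standard error (SE). The biological coefficient of variation was 129% over all small RNAs and 45.81% among known microRNAs alone. The second fit is quoted beside the first for some results only, so a value given without it may differ between the fits.

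The 20 lists of microRNAs were fixed by cell type, family or process before the data were examined. By cell type they are epithelium in general (miR-200 family), absorptive gut epithelium, enteroendocrine cells, smooth muscle, fibroblasts and mesenchyme, endothelium, myeloid cells, leukocytes, red blood cells, neurons, and liver with pancreas. By family or process they are inflammation, the miR-17-92 clusters, let-7, miR-34 (p53), hypoxia, miR-29 with miR-30, the HOX clusters, the DLK1-DIO3 cluster, and microRNAs abundant in milk. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over lists within a contrast. Camera sets a list against all other small RNAs, so a shift of known microRNAs as a class moves every list. Members of a list may share a cluster or near-identical sequence, so a count of members is not a count of independent results. Lists also share members, with 5 of 11 tested milk members, 6 of 10 for inflammation and 3 of 7 for leukocytes in another list. A count of lists is therefore not a count of independent results either. Shares of counts were compared by an exact permutation test, two-sided, in which 20 relabelings allow no p under 0.1.

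The microRNAs named follow a rule set at the same time. For each contrast against feeding it takes microRNAs past the threshold with groups that do not overlap, up to 10 in each direction, and where fewer pass, the 10 known microRNAs of smallest p. For contrasts between weaned groups and the test among groups it takes the 5 of smallest p. It also takes the 10 most abundant microRNAs and, of each list, the members past the threshold and the 3 most abundant members. Other small RNAs are named by identifier, 2 in each direction at most. Coordinates are those of the precursor in the RefSeq annotation of Sscrofa 11.1, where 66 of the 71 microRNAs named had a match by name, and give the span only. Fold changes are printed for the microRNAs of smallest p or past the threshold and for the top members of lists that passed both over all small RNAs and among known microRNAs alone. That last restriction was chosen after the results were seen, because the folds of other list members often changed sign with the settings, and those members are given as levels. The closing section gives the count of those sign changes. Outside this rule, the fold of miR-429 is also given, as the only tested member of the miR-200 family.

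The same steps were tested on simulated counts for 7 days of weaning against feeding. Over 2453 small RNAs, 0% of those changed 2-fold, 0% of those changed 4-fold and 1.5% of those changed 8-fold were recovered, with 1 call in all and 0 false calls. Over 295 known microRNAs alone, the shares were 20%, 80% and 90%, with 22 calls, of which 3 were false. A simulated list of 6 members moved 2-fold was recovered, and 0 of 12 unmoved lists were called. The list simulation used known microRNAs alone and drew each microRNA independently. It therefore cannot show false calls from members that move together or from a shift of known microRNAs as a class.

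The alternatives were DESeq2 1.42.0, DESeq2 size factors, no TMM factors, other filters, limma on log2 TPM, known microRNAs alone, and leaving out each library. Others were chosen after the data were seen, among them known microRNAs alone without replicate 1 of the group weaned for 7 days. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.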

Results

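Small RNA was profiled in the small intestine of piglets still suckling after 21 days of age (feeding group) or weaned for 1, 3 or 7 days after that age, with 3 libraries per group. The series asks how weaning affects gene expression. Each library held 24670093 to 27784417 counts, of which 6987325 to 18331061 fell on known microRNAs, and 306 to 322 known microRNAs were detected per library.

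The 10 most abundant known microRNAs held 57.28% to 71.03% of the known microRNA counts of a library. Over all 12 libraries, miR-194b-5p and miR-192, both typical of gut epithelium, came first, at 93070 ± 63510 and 90810 ± 34240 normalised CPM (read counts scaled by library size, SD). They were followed by miR-191 (65450 ± 8673), miR-26a (55420 ± 13370), miR-21 (53310 ± 22410) and miR-143-3p (49270 ± 47780), the last a smooth muscle microRNA. The other members of the 10 were miR-92a (34790 ± 7645), let-7a (34680 ± 5413), miR-194a (30980 ± 27250) and miR-181a (22350 ± 6805). The order differed between groups, since after 7 days of weaning miR-191 stood at 55670 ± 5226 CPM and miR-194b-5p at 24060 ± 21880. Known microRNAs took 59.5% ± 9.3 of the counts in the feeding group and 42.4% ± 15 after 7 days of weaning (SD, n = 3; exact permutation test, p = 0.2), a difference of -17.17 percentage points that was -8.622 without replicate 1 of the group weaned for 7 days. Predicted piRNAs took 0.524% ± 0.0199 and 1.08% ± 0.146, where p = 0.1 by exact permutation is the smallest the design allows. Predicted microRNAs took 1.02% ± 0.202 and 1.99% ± 1.5, a difference of 0.967 percentage points that was 0.1067 without that library, and Rfam families took 11.04% ± 1.83 and 9.98% ± 2.23, a difference of -1.064 that turned to 0.1015 without it. Adjusted over the classes, the exact permutation p was 0.6 for Rfam families and 0.35 for each of the others. Replicate 1 of the group weaned for 7 days stood apart, with 25.3% of its counts on known microRNAs and 62.17% in exons, introns and intergenic sequence, and with a first principal component of 28.2 against -3.88 to 0.7 elsewhere.

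**Figure D1:**
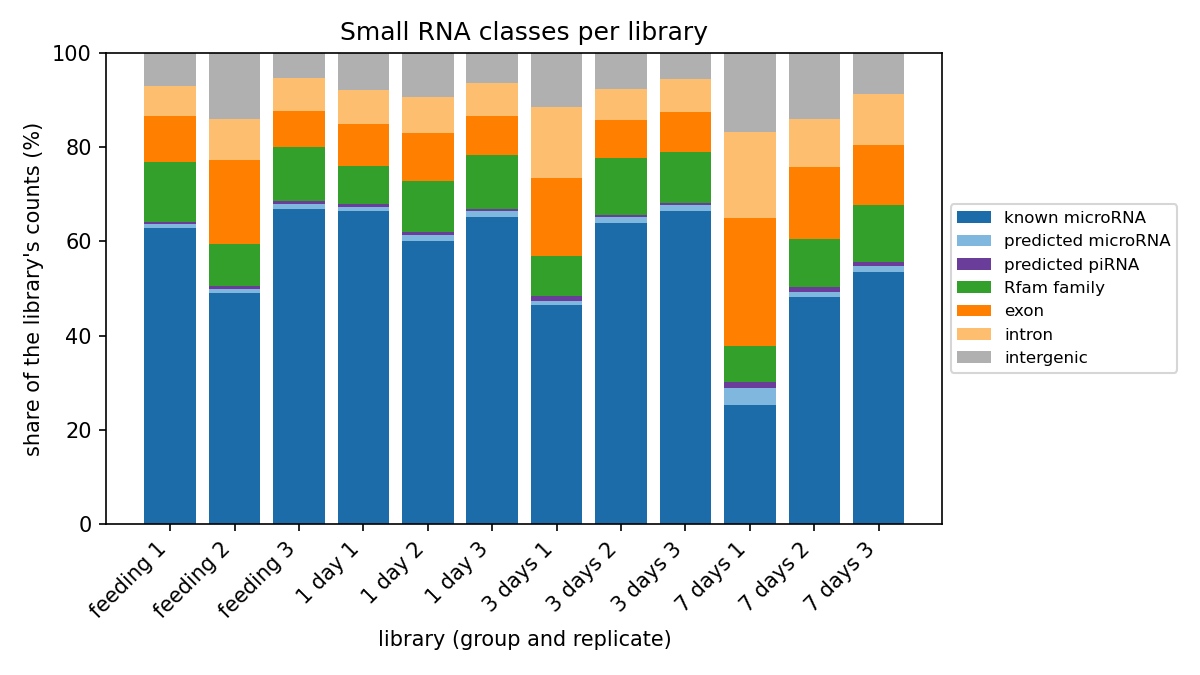
Share of each library's counts (percent) by class of small RNA and genomic region, for the 4 groups of 3 libraries. Known microRNAs fill 25.3% of replicate 1 of the group weaned for 7 days and up to 66.8% of other libraries.

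The first question was what differs 1 day after weaning. The list of absorptive gut epithelium microRNAs was lower as a group than in feeding piglets, with 5 of 5 members lower (camera, adjusted p = 0.00268, and adjusted p = 0.551 with an estimated correlation). Among them miR-192 stood at 77970 ± 24890 against 121900 ± 29640 CPM, and miR-194a at 12200 ± 4535 against 45420 ± 24930. MicroRNAs of the HOX clusters, which lie among the genes of body position, were higher as a group in 6 of 6 members (camera, adjusted p = 0.0192, and adjusted p = 0.551 with an estimated correlation), led by miR-10b at 7801 ± 1097 against 4158 ± 793. Smooth muscle microRNAs were higher as a group in 7 of 7 members (camera, adjusted p = 0.00631), and neuronal ones in 6 of 8 (camera, adjusted p = 0.0407), each with an adjusted p of 0.551 with an estimated correlation. The smooth muscle difference rested on replicate 1 of the group weaned for 1 day, in which miR-143-3p reached 200300 CPM; its log2 fold change was 1.31 ± 0.56 (SE) with that library and -0.02 without it. Without that library the smooth muscle and neuronal lists missed the threshold (camera, adjusted p = 0.808 and 0.225), and without feeding replicate 1 the gut epithelium, HOX and neuronal lists did (0.126, 0.197 and 0.126), as did HOX without replicate 3 of the group weaned for 1 day (0.213). Among known microRNAs alone the neuronal list missed the threshold too (camera, adjusted p = 0.0596).

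No single small RNA passed after 1 day. With edgeR, 0 of 2453 were past the adjusted threshold and 74 had an unadjusted p under 0.05, while DESeq2 gave 20 and limma 0. Adjusted over the list alone, 1 HOX cluster member passed and 0 members of the gut epithelium, smooth muscle and neuronal lists did. Of the known microRNAs of smallest p, each at an edgeR adjusted p of 0.847, 5 were lower after 1 day. The log2 difference was -2.71 ± 0.77 (SE) for miR-218b (8.17 ± 2.99 against 53.7 ± 37.3 CPM), -1.90 ± 0.79 for miR-194a, -1.48 ± 0.63 for miR-874 and -0.65 ± 0.28 for miR-192, while miR-676-3p stood at 1126 ± 136.2 against 2258 ± 825. The other 5 were higher, with 0.91 ± 0.26 for miR-10b, 2.16 ± 0.70 for miR-129a-5p, 1.11 ± 0.45 for miR-99a, 3.26 ± 1.34 for miR-224 and 0.77 ± 0.33 for miR-451, a microRNA of red blood cells. In the group weaned for 1 day, miR-224 rested on replicate 2 (log2 0.916 without it) and miR-99a on replicate 1 (0.249 without it). In the feeding group, miR-874 rested on replicate 1 (-0.397 without it), miR-129a-5p was 2.86 without replicate 1 and miR-218b -2.1 without replicate 3. Of the other small RNAs, novel_pir227 had the smallest p among those higher and novel_pir2394 among those lower.

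After 3 days of weaning the gut epithelium list did not pass against feeding (camera, adjusted p = 0.368, 4 of 5 members lower), nor did it pass against 1 day (0.121, 4 of 5 higher). Among its members miR-192 stood at 112600 ± 8630, miR-194b-5p at 116200 ± 8304, miR-194a at 60970 ± 15660, miR-215 at 1760 ± 219.5 and miR-194b-3p at 7.242 ± 0.353 CPM. The HOX cluster microRNAs were above feeding in 6 of 6 members, with miR-10a-5p at 9516 ± 2049 against 5033 ± 228 and miR-10b at 7023 ± 1238 against 4158 ± 793. Over all small RNAs the list missed the threshold (camera, adjusted p = 0.0757), and among known microRNAs alone it passed (camera, adjusted p = 0.00287, and adjusted p = 0.335 with an estimated correlation). Adjusted over the list alone, 2 members passed. Leukocyte microRNAs were below feeding in 7 of 7 members, short of the threshold (camera, adjusted p = 0.0750). No list passed over all small RNAs.

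Single small RNAs did not pass after 3 days either. With edgeR, 0 of 2453 were past the adjusted threshold and 13 known microRNAs, 27 predicted microRNAs, 99 predicted piRNAs and 6 Rfam families had an unadjusted p under 0.05, while DESeq2 gave 35 and limma 0. The 10 known microRNAs of smallest p shared an edgeR adjusted p of 0.565. Their log2 differences were -1.52 ± 0.45 (SE) for miR-671-5p, -1.04 ± 0.33 for miR-676-3p (1100 ± 8.39 against 2258 ± 825 CPM), -1.93 ± 0.63 for miR-874, -1.66 ± 0.60 for miR-365-3p and -0.83 ± 0.33 for miR-140-5p. On the higher side they were 3.47 ± 1.04 for miR-490-5p, 0.92 ± 0.31 for miR-10a-5p, 0.76 ± 0.26 for miR-10b, 1.36 ± 0.50 for miR-124a and 0.72 ± 0.27 for miR-125a. Without feeding replicate 1 the log2 difference was -0.846 for miR-874 and -0.97 for miR-365-3p, and without replicate 2 of the group weaned for 3 days it was 2.545 for miR-490-5p. Of the other small RNAs, novel_pir227 and novel_pir1598 had the smallest p among those higher, and novel_mir979 and novel_mir11 among those lower.

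After 7 days of weaning miR-676-3p fell, from 2258 ± 825 CPM in feeding piglets to 279 ± 73.5 (SD, n = 3). It was the only small RNA of 2453 past the threshold (log2 fold change -3.02 ± 0.35 (SE), edgeR adjusted p = 0.00572), and it was lower in each of the 3 weaned libraries than in any feeding library. Its precursor gene, MIR676-1, lies on chromosome X from 56083372 to 56083451, within the span of EDA, a ligand gene of ectodermal development. The other arm, miR-676-5p, stood at 1.06 ± 0.40 against 5.09 ± 2.12 CPM, short of the threshold. The absorptive gut epithelium microRNAs were lower as a group in 5 of 5 members (camera, adjusted p = 3.43e-09, and adjusted p = 0.0700 with an estimated correlation), with a median log2 difference of -2.57. Of these, miR-194a, miR-194b-5p and miR-215 were among 13 microRNAs more than 4-fold below each of the other 11 libraries in replicate 1 of the group weaned for 7 days. Without that library the list passed among known microRNAs alone, with a median log2 difference of -1.852 (camera, adjusted p = 9.54e-11, and adjusted p = 0.0856 with an estimated correlation). The epithelial microRNA miR-429 was below feeding as well, short of the threshold (log2 -1.02 ± 0.43 (SE), edgeR adjusted p = 0.470). Among known microRNAs alone without replicate 1 of the group weaned for 7 days, its log2 difference was -0.55. MiR-192 stood at 50730 ± 7314 against 121900 ± 29640, miR-194b-5p at 24060 ± 21880 against 153200 ± 83960, and miR-194a at 5318 ± 4388 against 45420 ± 24930. None of the 5 list members passed over all small RNAs, and 5 passed when adjusted over the list alone. The precursors of miR-192 and miR-194a lie close together on chromosome 2 (7285466 to 7285746). Those of miR-215 and miR-194b lie close together on chromosome 10 (9704606 to 9704987). These members may therefore move together, and their number is not a number of independent results.

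**Figure D2:**
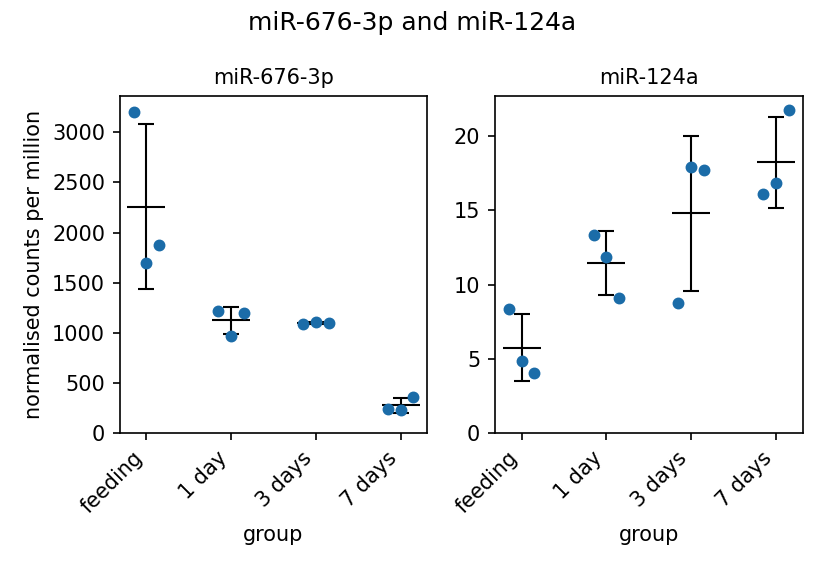
Normalised CPM of miR-676-3p and miR-124a in each of the 12 libraries (points), with the mean and SD of each group (bars). The 3 libraries weaned for 7 days hold 233 to 364 CPM of miR-676-3p, and the feeding libraries 1697 to 3205.

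Of the other microRNAs of smallest p after 7 days, each at an edgeR adjusted p of 0.470, most were lower than in feeding. The log2 difference was -1.26 ± 0.28 (SE) for miR-192, -3.09 ± 0.83 for miR-194a, -2.67 ± 0.84 for miR-194b-5p and -1.74 ± 0.61 for miR-194b-3p. It was -1.17 ± 0.30 for miR-22-3p (6199 ± 1264 against 13900 ± 4023 CPM), -1.84 ± 0.52 for miR-22-5p, -1.86 ± 0.63 for miR-874 and -2.25 ± 0.78 for miR-676-5p. The neuronal microRNA miR-124a was higher, by 1.66 ± 0.51, at the low level of 18.24 ± 3.068 against 5.756 ± 2.275 CPM. Without feeding replicate 1 miR-874 was at -0.802, and without replicate 3 of the group weaned for 7 days miR-194a was at -3.709 and miR-194b-5p at -3.518. Among known microRNAs tested alone, miR-676-3p (log2 -2.73 ± 0.30 (SE), edgeR adjusted p = 0.000349) and miR-124a (1.94 ± 0.36, edgeR adjusted p = 0.0259) passed, and the neuronal list was higher in 6 of 8 members (camera, adjusted p = 0.0143, and adjusted p = 0.139 with an estimated correlation). The most abundant neuronal member, miR-128, was lower, at 633.2 ± 90.21 against 1039 ± 122.8 CPM. The next, miR-9, stood at 65.35 ± 24.29 against 59.99 ± 14.82. In the fit of known microRNAs alone miR-192 was at log2 -0.96 ± 0.30 (SE). Without replicate 1 of the group weaned for 7 days, the neuronal list missed the threshold among known microRNAs alone (camera, adjusted p = 0.0527), and 7 known microRNAs passed. These were miR-676-3p, miR-194a, miR-194b-5p and miR-215 below feeding, and miR-124a, miR-195 and miR-204 above it.

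The edgeR count of 1 for 7 days against feeding compares with 243 small RNAs at an unadjusted p under 0.05, with 42 by DESeq2 and with 2 by limma. The call of miR-676-3p ended in a fit of only the feeding and 7-day libraries (edgeR adjusted p = 0.317) and without replicate 2 of the group weaned for 7 days (edgeR adjusted p = 0.0827), with a log2 fold change of -3.02 and -2.91. Over all its alternatives the adjusted p ran from 1.1e-15 to 0.317. Of the other small RNAs, novel_pir1842 and novel_pir227 had the smallest p among those higher, and novel_pir1576 and novel_mir521 among those lower.

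**Figure D3:**
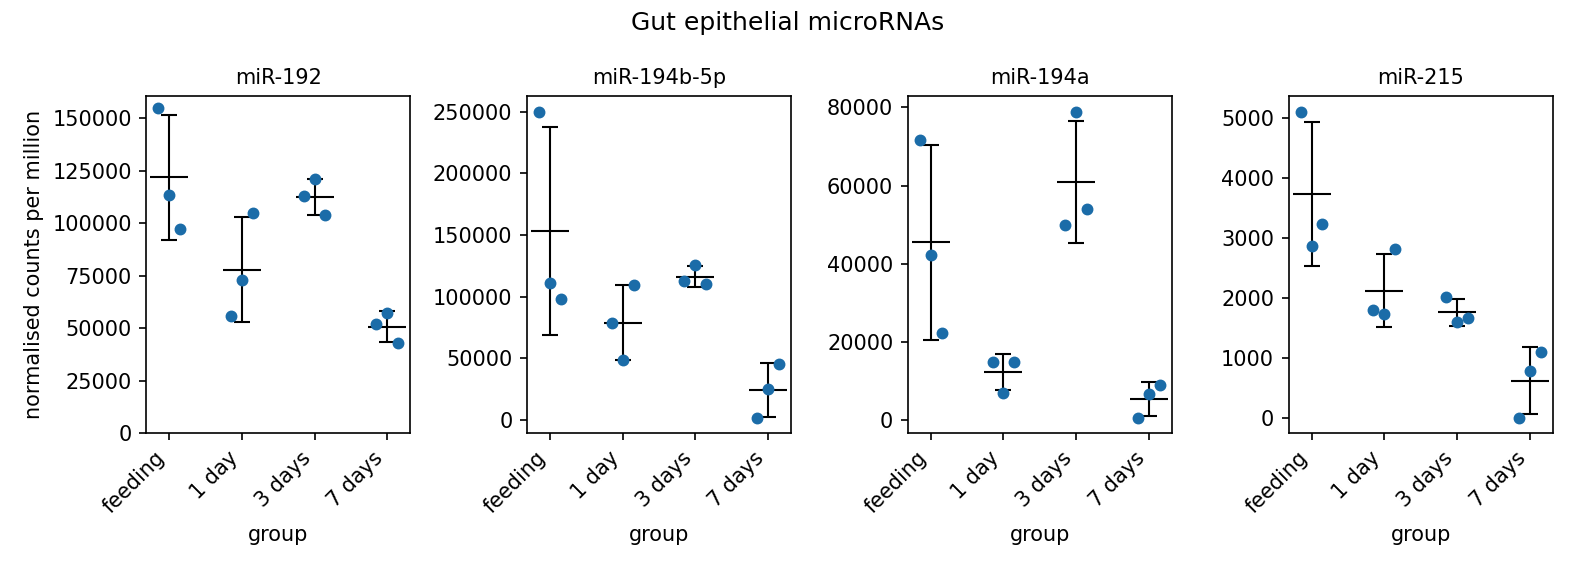
Normalised CPM of miR-192, miR-194b-5p, miR-194a and miR-215 in each of the 12 libraries (points), with the mean and SD of each group (bars). The libraries weaned for 7 days hold 42820 to 57250 CPM of miR-192, and the feeding libraries 97250 to 154800.

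Another 6 lists were lower as groups after 7 days against all small RNAs, though none with an estimated correlation, at a time when known microRNAs as a class had a median log2 difference of -0.24, predicted piRNAs 0.61 and Rfam families 0.65. They were microRNAs abundant in milk (11 of 11 lower, camera adjusted p = 0.00209), the DLK1-DIO3 cluster (12 of 13, 0.00266), miR-29 with miR-30 (12 of 13, 0.00569), the HOX clusters (6 of 6, 0.00569), the miR-17-92 clusters (10 of 13, 0.00871) and let-7 (8 of 9, 0.0307). With an estimated correlation the adjusted p was 0.158 for milk, 0.365 for DLK1-DIO3, 0.299 for miR-29 with miR-30, 0.358 for HOX, 0.365 for miR-17-92 and 0.365 for let-7. None of these 6 passed among known microRNAs alone, and without replicate 1 of the group weaned for 7 days the miR-17-92 list turned upward there (camera, adjusted p = 0.882). With all libraries, the HOX member miR-10a-5p was higher among known microRNAs alone (log2 0.214 ± 0.241 (SE)). Over all small RNAs, miR-17-92 and let-7 missed the threshold without that library (camera, adjusted p = 0.202 and 0.0619), and miR-17-92, let-7 and DLK1-DIO3 without feeding replicate 3 (0.0704, 0.0508 and 0.0704). Adjusted over the list alone, 2 members of the milk list passed (miR-22-3p and miR-22-5p) and 0 of the others. The milk list shared 5 members with other lists, miR-29 with miR-30 shared 3 and let-7 2, so these lists were not independent.

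Comparisons between the weaned groups ask whether levels differ between lengths of weaning, and each tests the difference itself. Age goes with days of weaning in these groups, so length of weaning and age cannot be told apart. From 1 to 3 days, leukocyte microRNAs (camera, adjusted p = 0.000455), smooth muscle (0.00256) and the DLK1-DIO3 cluster (0.00411) were lower as groups, with adjusted p of 0.470, 0.570 and 0.570 with an estimated correlation. Smooth muscle missed the threshold without replicate 1 of the group weaned for 1 day (camera, adjusted p = 0.312), and DLK1-DIO3 without replicate 1 of the group weaned for 3 days (0.515). The 5 known microRNAs of smallest p (edgeR adjusted p = 0.578) were miR-218b at 68.4 ± 57.9 against 8.17 ± 2.99 CPM (log2 3.064, and 2.097 without replicate 2 of the group weaned for 3 days), miR-194a at 60970 ± 15660 against 12200 ± 4535, miR-365-3p at 7.64 ± 2.602 against 27.1 ± 8.43, miR-20b at 171 ± 38.7 against 372 ± 103 and miR-142-5p at 56.3 ± 18.1 against 118 ± 17.8. From 3 to 7 days, the gut epithelium list (camera, adjusted p = 7.53e-08) and the HOX list (4.92e-07) were lower in 5 of 5 and 6 of 6 members, with adjusted p of 0.0911 and 0.107 with an estimated correlation. Adjusted over the list alone, 3 and 5 of their members passed. MiR-676-3p stood at 279 ± 73.5 against 1100 ± 8.39 CPM (edgeR adjusted p = 0.166, and 0.0189 among known microRNAs alone), miR-10b at 2657 ± 245 against 7023 ± 1238 (0.166), miR-194a and miR-192 had 0.526 and miR-26a 0.632, where the log2 difference of miR-194a was -3.519, and -4.135 without replicate 3 of the group weaned for 7 days. From 1 to 7 days, miR-676-3p and miR-10b had an edgeR adjusted p of 0.106 (0.0374 and 0.0600 among known microRNAs alone), and miR-129a-5p, let-7g and miR-196b-5p 0.441, with a log2 difference of miR-196b-5p between -6.509 (without replicate 2 of the group weaned for 7 days) and -2.729 (without replicate 3 of the group weaned for 1 day). For 3 against 1 day, 7 against 1 and 7 against 3, edgeR called 0 over all small RNAs, with 118, 247 and 181 at an unadjusted p under 0.05, and 0, 1 and 1 among known microRNAs alone. DESeq2 called 27, 58 and 16, and limma 0, 2 and 0.

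**Figure D4:**
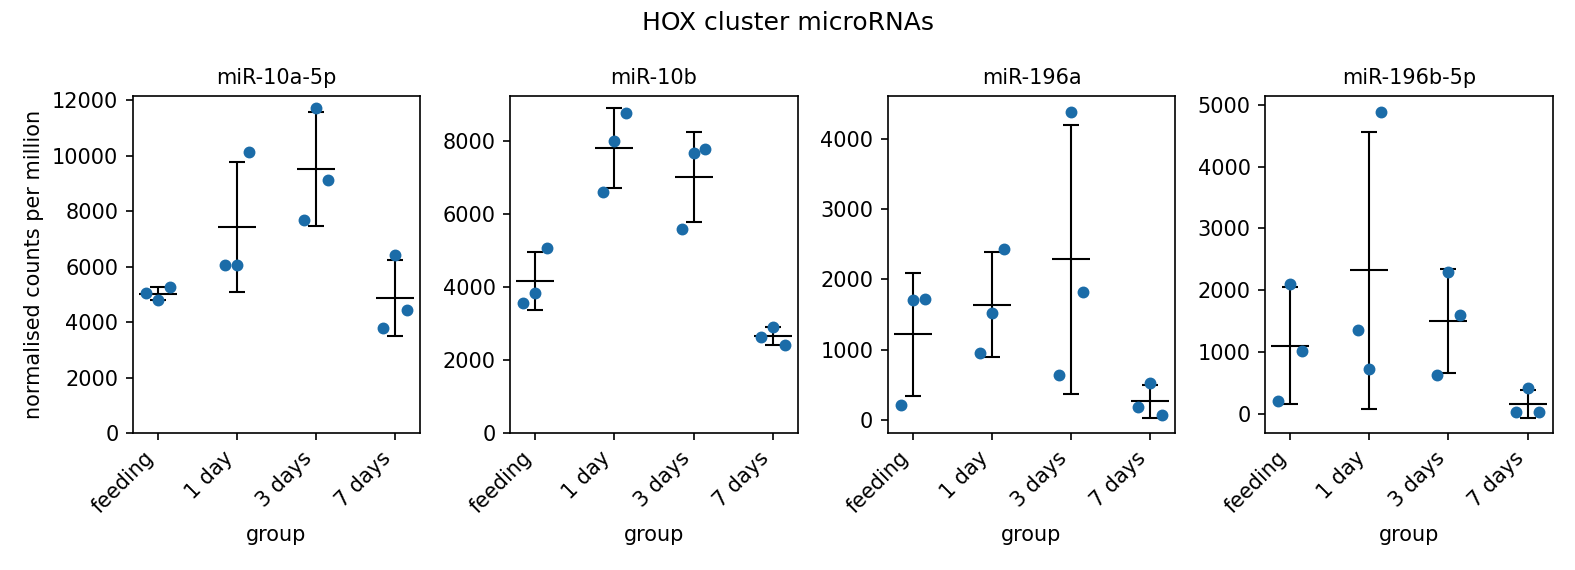
Normalised CPM of the HOX cluster microRNAs miR-10a-5p, miR-10b, miR-196a and miR-196b-5p in each of the 12 libraries (points), with the mean and SD of each group (bars). The libraries weaned for 7 days hold 2421 to 2910 CPM of miR-10b, and those weaned for 3 days 5595 to 7793.

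Among the 4 groups together, miR-676-3p came first (edgeR adjusted p = 0.0602, and 0.00348 among known microRNAs alone), followed by miR-10b (0.366), miR-192 and miR-194a (0.559) and miR-218b (0.595). With edgeR, 0 of 2453 small RNAs passed and 175 had an unadjusted p under 0.05, while DESeq2 gave 40 and limma 0.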

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

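The comparisons between weaned groups were planned, while the tests of explanations, their predictions and those for other splits of the libraries were set after the results had been seen. The results below stand out because levels differed between durations of weaning. The share of reads in introns is added because it did not overlap between feeding and 7 days. Age goes with days of weaning among the weaned groups, and no feeding group is labelled for each duration. The contrasts between weaned groups therefore cannot separate weaning from age.

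From 1 to 3 days of weaning, 3 lists were lower as groups by camera, leukocytes (adjusted p = 0.000455), smooth muscle (0.00256) and the DLK1-DIO3 cluster (0.00411), with adjusted p of 0.470, 0.570 and 0.570 with an estimated correlation. The smooth muscle level at 1 day was carried by replicate 1 of that group, and without it the list missed the threshold (camera, adjusted p = 0.312 from 1 to 3 days and 0.224 from 1 to 7 days). Without replicate 1 of the group weaned for 3 days, DLK1-DIO3 missed it from 1 to 3 days (0.515). From 1 to 7 days, 10 lists were lower as groups by camera, and none of them passed with an estimated correlation (adjusted p from 0.2003 to 0.309). These were the HOX clusters (adjusted p = 2.2e-05), DLK1-DIO3 (4.61e-05), gut epithelium (0.000554), let-7 (0.00372), milk (0.0043), smooth muscle (0.0043), miR-17-92 (0.00474), miR-29 with miR-30 (0.00474), leukocytes (0.00532) and inflammation (0.0118), and miR-17-92 missed the threshold without replicate 1 of the group weaned for 7 days (0.0524). Known microRNAs as a class had a median log2 difference of -0.471 in this contrast and predicted piRNAs 0.877. Among known microRNAs alone only 3 of the 10 lists passed by camera, HOX (adjusted p = 0.00482), DLK1-DIO3 (0.00629) and gut epithelium (0.0471), with adjusted p of 0.624, 0.648 and 0.648 with an estimated correlation. Among known microRNAs alone, miR-676-3p was lower after 7 days than after 1 day (edgeR adjusted p = 0.0374) and than after 3 days (edgeR adjusted p = 0.0189). From 3 to 7 days the gut epithelium list (camera, adjusted p = 7.53e-08) and the HOX list (4.92e-07) were lower, with adjusted p of 0.0911 and 0.107 with an estimated correlation. Reads in introns, which name no small RNA, took 13.13% of the counts after 7 days on average, with each library above the highest feeding library. Chance gives this in 5% of comparisons of 3 against 3, and in 10% when either direction counts. Several classes were compared, and adjusted over them the exact permutation p for introns was 0.35. Replicate 1 held 18.28%, against 10.25% and 10.86% in the other libraries weaned for 7 days. Replicate 1 of the group weaned for 3 days held 15.05%.

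In replicate 1 of the group weaned for 7 days, 13 of 162 microRNAs with a median of at least 50 CPM of known microRNAs elsewhere stood more than 4-fold below each of the other 11 libraries, while no other library had more than 1 such name. A shift of reads between miR-194a and miR-194b is argued against, since their number's sum was 5135 CPM of known microRNAs against at least 44360 elsewhere. A loss that grows gradually with the exon, intron and intergenic share is argued against only up to the shares that other libraries reached. The 13 names, chosen without the 3 libraries next highest in that share, had a lowest median log2 deviation of 0.03 there. Those libraries held 39.38% to 43.18%, against 62.17% in replicate 1 itself, so a loss that starts between these shares was not tested. Chosen without the other 2 libraries of the group, the 10 names outside the gut epithelium list had medians of 0.201 and 0.323 there, which argues against 7 days of weaning for them, while miR-194a, miR-194b-5p and miR-215 had -1.743 and -0.571 against -5.453 in the library itself, so weaning may hold part of their loss and stays open. Shifts to sibling names stay open for the other 5 numbers, whose sums lie inside the range of the other libraries in 5 of 5 cases but consist mostly of other names anyway. Predicted microRNAs held an excess worth 75.57% of the missing counts. Only identifiers above their median share elsewhere were summed, and the same sum was not made for other libraries. The excess lay largely in novel_mir2 (474023 counts, at most 48967 elsewhere) and novel_mir4 (150045, at most 11485 elsewhere). A different assignment of reads to names in this library may account for part of the pattern, which the deposited lists cannot settle.

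MiR-192, miR-194 and miR-215 were lower after 7 days of weaning than in feeding piglets, and age, which may go with days of weaning here, stays open and untested. The library that stands apart is argued against as the whole cause, since without it the list passed among known microRNAs alone (camera, adjusted p = 9.54e-11). With an estimated correlation the list did not pass (camera, adjusted p = 0.0856). The 3 list members far below in that library had median log2 deviations of -1.743 and -0.571 in the group's other libraries, against -5.453 in it. That library may therefore carry part of the fall. Reads moved between miR-194a and miR-194b-5p are argued against as well, since the log2 ratio of their summed group means was -2.07. This ratio includes the library that stands apart. The group's other libraries had sums of 44350 and 95140 CPM of known microRNAs, against 143900 to 286400 in the feeding group. A lower share of epithelial cells may contribute and stays open, because miR-429, the only tested member of the miR-200 family, had a log2 difference of -1.02 ± 0.43 (SE) over all small RNAs and libraries (edgeR unadjusted p = 0.0356, adjusted p = 0.470) and of -0.55 ± 0.32 among known microRNAs without that library (unadjusted p = 0.117). In that last fit the median log2 difference was 0.4 for smooth muscle, 0.399 for fibroblasts and mesenchyme, 0.619 for red blood cells, 0.854 for neurons and 0.071 for leukocytes, and none of these lists passed (camera, adjusted p from 0.0527 to 0.920).

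MicroRNAs of the HOX clusters were lower after 7 than after 3 days of weaning. Libraries taken from different sites along the intestine could give such a pattern, and the summed level of miR-196 varied 10.1-fold within the feeding group, against 1.39-fold for miR-10b, but only 1.56-fold without feeding replicate 1. With miR-196 as a covariate among known microRNAs, the log2 difference of miR-10b went from -1.12 ± 0.24 to -0.71 ± 0.35 (SE), so the difference became smaller and its error larger, and site and weaning cannot be told apart for this list. The same covariate left miR-676-3p past the threshold for 7 days against feeding (log2 -3.04 ± 0.28 (SE), edgeR adjusted p = 0.000133), which argues against site, as far as miR-196 tracks it, as the whole cause of that fall. Days of weaning and age stay open as well.

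Each contrast of 3 against 3 libraries allows only 10 splits, which are too few for a share under 0.05. For single small RNAs the real count and the highest of the other splits were 1 and 0 for 7 days against feeding, and 0 and 0 for the other 5 contrasts, so that in those 5 all 10 splits tied. Among known microRNAs alone they were 2 and 0 for 7 days against feeding, 1 and 0 for 7 against 1 day and for 7 against 3 days, and 0 and 0 for the others. For lists they were 4 and 6 for 1 day against feeding, 0 and 3 for 3 days, 7 and 4 for 7 days, 3 and 4 for 3 against 1 day, 10 and 6 for 7 against 1 day, and 2 and 2 for 7 against 3 days. Splits with as many lists numbered 4, 10, 1, 5, 1 and 2 in that order. Among the 4 groups, 100 splits were drawn. The real count of 0 small RNAs was reached in 100 of them, with a highest other count of 4. The real count of 1 known microRNA was reached in 9, with a highest other count of 1, so chance cannot be excluded for either.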

How the results depend on the processing

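Alternatives chosen after seeing the data were edgeR robust, the genomic share as a covariate, letter variants summed, the level of miR-196 as a covariate, known microRNAs alone without replicate 1 of the group weaned for 7 days, and, for lists, known microRNAs alone, DESeq2 size factors and each library left out. Limma on log2(TPM + 1) was the test planned had the files held no raw counts, and was not planned as an alternative. The cause of the changes below was not tested, except that known microRNAs alone and no filter change the number of small RNAs tested. Results of 7 days against feeding come first in what follows. MiR-676-3p kept its direction in each alternative (log2 from -3.27 to -2.33), and its call in all but a fit of only the compared groups, which gave 0 calls, and without weaned_7d replicate 2.

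Counts of small RNAs depended most on the tool and the filter. DESeq2 gave 42 for 7 days against feeding (32 higher, 10 lower), 20 for 1 day (7 higher, 13 lower), 35 for 3 days (29 higher, 6 lower), 27 for 3 against 1 day (25 higher, 2 lower), 58 for 7 against 1 day (47 higher, 11 lower), 16 for 7 against 3 days (5 higher, 11 lower) and 40 among the 4 groups. No filter gave 1.5e+02 (130 higher, 16 lower), 23, 56, 47, 149, 1.3e+02 (95 higher, 32 lower) and 273 in the same order. Known microRNAs alone gave 2, 1 for 7 against 1 day, 1 for 7 against 3 days and 1 among the groups. Known microRNAs alone without replicate 1 of the group weaned for 7 days gave 7 (3 higher, 4 lower), 1 for 3 against 1 day, 7 for 7 against 1 day, 4 for 7 against 3 days and 6 among the groups. Letter variants summed gave 2, 2 for 7 against 1 day, 1 for 7 against 3 days and 1 among the groups. A TPM of at least 10 in at least 3 libraries gave 2 for 7 against 1 day, 1 for 7 against 3 days and 1 among the groups. Robust edgeR gave 2 for 7 against 1 day and 1 among the groups, and DESeq2 size factors 1 among the groups. Limma gave 2 for 7 days against feeding with a pseudocount of 0.1, of 1, and of 1 with robust estimation. For 7 against 1 day it gave 1, 2 and 2 in these settings and 1 after quantile normalization, and for 7 against 3 days 1 with a pseudocount of 0.1.

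Lists depended on the correlation between members. With an estimated correlation 0 lists passed for 7 days against feeding, 1 day against feeding, 3 against 1 day, 7 against 1 day and 7 against 3 days. Fry gave 2 for 7 days, 0 for 1 day, 0 for 3 against 1 day and 5 for 7 against 1 day. Known microRNAs alone gave 2 for 7 days, 1 for 3 days and 3 for 7 against 1 day, and also without replicate 1 of the group weaned for 7 days 1, 1 and 3. No TMM factors gave 1 for 7 days and 4 for 7 against 1 day. The miR-17-92 list turned upward in known microRNAs alone without that replicate, with camera adjusted p of 0.882 for 7 days against feeding and 0.735 for 7 against 1 day.

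With each library left out in turn, the count of small RNAs for 7 days against feeding ran from 0 (without weaned_7d replicate 2) to 1. Lists ran from 4 (without feeding replicate 3) to 9 (without feeding replicate 1) for 7 days, from 1 (without feeding replicate 1) to 7 (without weaned_7d replicate 1) for 1 day, and from 0 to 5 (without feeding replicate 2) for 3 days. They ran from 2 to 6 (without weaned_7d replicate 1) for 3 against 1 day, and from 2 to 7 (without weaned_3d replicate 1) for 7 against 3 days. For 1 day against feeding, log2 ran from -0.068 (without feeding replicate 1) to 0.77 for miR-196a, and, lowest without weaned_1d replicate 1, from -0.13 to 1.80 for miR-133a-3p and from -0.022 to 1.71 for miR-143-3p. The difference in Rfam share ran from 0.102 percentage points (without weaned_7d replicate 1) to -2.12.

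Of the 51 fold changes tracked here over the alternatives, 1420 refits kept direction and side of the threshold, 50 moved past it, 2 fell short of it and 3 changed sign. The naming rule gave 173 fold changes in all, and 325 of their 4942 refits, over 74 of them, changed sign. The folds concerned reached 1.94 as reported, and in 2 of these refits the fold as reported had an unadjusted p under 0.05. That is why members of other lists are given as levels. No paired analysis was made, because the labels do not say whether libraries of different groups belong together. The library numbers in the labels rise with days of weaning among the weaned groups, and what they stand for is not given.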

Other observations

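The share test of miR-194a was chosen after the values were seen. Several lists did not pass for 7 days against feeding. Their camera adjusted p was 0.41 for smooth muscle, 0.222 for fibroblasts and mesenchyme, 0.0904 for leukocytes, 0.492 for red blood cells, 0.37 for neurons and 0.114 for inflammation. Levels are given in normalised CPM for feeding piglets and after 1, 3 and 7 days in turn, as mean ± SD (n = 3), and the most abundant members of each list are named, up to 3. Of these, let-7c, miR-145-5p, miR-194a, miR-194b-5p, miR-199b-3p and miR-363 were far below every other library in replicate 1 of the group weaned for 7 days. Their means at 7 days are pulled down by that library, as for let-7c, which ran from 981.8 to 16480 CPM in that group. The myeloid list had 0 members in the files.

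Endothelium had miR-126-3p at 13970 ± 1082, 13090 ± 2932, 14940 ± 2920 and 13000 ± 1785, and miR-126-5p at 157.5 ± 41.89, 183.1 ± 50.65, 127.9 ± 1.768 and 201.9 ± 67.53. Epithelium in general had miR-429 at 6276 ± 1264, 5086 ± 1848, 6741 ± 1196 and 3098 ± 1609, and enteroendocrine cells miR-7 at 1972 ± 452.6, 2231 ± 699.5, 1546 ± 354.2 and 3408 ± 2544. Gut epithelium had miR-194b-5p at 153200 ± 83960, 78850 ± 30260, 116200 ± 8304 and 24060 ± 21880, miR-192 at 121900 ± 29640, 77970 ± 24890, 112600 ± 8630 and 50730 ± 7314, and miR-194a at 45420 ± 24930, 12200 ± 4535, 60970 ± 15660 and 5318 ± 4388. Smooth muscle had miR-143-3p at 36450 ± 4664, 90640 ± 94980, 38220 ± 6867 and 31780 ± 3483, miR-145-5p at 1031 ± 147.3, 1870 ± 1174, 969.7 ± 66.87 and 838 ± 754.1, and miR-133a-3p at 156.5 ± 38.46, 410.6 ± 463.8, 123.1 ± 31.67 and 175.7 ± 67.27. Fibroblasts and mesenchyme had miR-199a-3p at 3778 ± 2533, 4448 ± 2964, 6689 ± 1228 and 2448 ± 1762, miR-199b-3p at 3038 ± 2960, 3007 ± 2889, 1693 ± 226.3 and 2590 ± 3671, and miR-199a-5p at 1128 ± 162.5, 1412 ± 306.3, 1587 ± 339.9 and 1305 ± 78.26. Leukocytes had miR-150 at 4684 ± 1031, 6669 ± 973.4, 3136 ± 2115 and 5445 ± 178, miR-363 at 3116 ± 1154, 3697 ± 622, 2938 ± 1091 and 1505 ± 1230, and miR-155-5p at 962.1 ± 367.4, 1598 ± 73.83, 746.7 ± 218.2 and 675.2 ± 466.5. Red blood cells had miR-451 at 2138 ± 752.3, 3651 ± 587, 3213 ± 477.7 and 2919 ± 646.4, miR-486 at 25.77 ± 8.074, 28.27 ± 2.982, 24.97 ± 7.76 and 24.94 ± 11.27, and miR-144 at 0.4956 ± 0.1161, 0.4195 ± 0.1351, 0.2919 ± 0.3364 and 3.743 ± 5.263. Neurons had miR-128 at 1039 ± 122.8, 1001 ± 374.6, 1049 ± 210.3 and 633.2 ± 90.21, miR-9 at 59.99 ± 14.82, 110.8 ± 60.6, 60.31 ± 20.12 and 65.35 ± 24.29, and miR-9-2 at 8.848 ± 13.16, 24.95 ± 12.6, 16.92 ± 4.703 and 21.93 ± 9.324. Liver and pancreas, which gut samples should lack, had miR-122 at 20.28 ± 7.747, 15.05 ± 3.096, 14.85 ± 2.492 and 15.88 ± 12.71, and miR-216 at 0.3067 ± 0.2738, 1.066 ± 1.451, 0.2298 ± 0.1496 and 0.4086 ± 0.4822.

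Inflammation had miR-21 at 55330 ± 9521, 58660 ± 19190, 59490 ± 16650 and 39750 ± 40530, miR-146a-5p at 3419 ± 918.6, 4976 ± 372.9, 3744 ± 1308 and 2829 ± 353.6, and miR-31 at 2652 ± 970.1, 1749 ± 1141, 3171 ± 792.3 and 1660 ± 255.2. Hypoxia had miR-210 at 36.16 ± 9.328, 35.85 ± 13.61, 23.02 ± 7.317 and 27.22 ± 8.65, and the p53 list miR-34a at 1983 ± 670.9, 2417 ± 358, 2121 ± 372.6 and 1445 ± 148.8, and miR-34c at 0.8948 ± 0.4162, 0.7066 ± 0.4487, 0.6356 ± 0.3544 and 3.453 ± 4.448. The miR-17-92 clusters had miR-92a at 33940 ± 2504, 33950 ± 6488, 40750 ± 12040 and 30490 ± 6709, miR-363 as above, and miR-92b-3p at 1663 ± 451.7, 2098 ± 365.1, 1525 ± 559.3 and 1253 ± 208.9. The let-7 family had let-7a at 33030 ± 2915, 40100 ± 3377, 35040 ± 5885 and 30570 ± 5747, let-7c at 15180 ± 540.2, 17730 ± 1253, 19090 ± 2790 and 10250 ± 8183, and let-7g at 12550 ± 1150, 13070 ± 1062, 10990 ± 1719 and 7903 ± 1301. The miR-29 and miR-30 families had miR-30d at 5781 ± 783.1, 5588 ± 2441, 5586 ± 957.7 and 4034 ± 1028, miR-29a at 1962 ± 61.13, 1994 ± 236.3, 1891 ± 115.6 and 1513 ± 354, and miR-30a-5p at 1760 ± 632.5, 1257 ± 277, 1243 ± 338 and 1023 ± 883.8. The HOX clusters had miR-10a-5p at 5033 ± 228, 7430 ± 2354, 9516 ± 2049 and 4881 ± 1368, miR-10b at 4158 ± 793.2, 7801 ± 1097, 7023 ± 1238 and 2657 ± 245.1, and miR-196a at 1217 ± 869.2, 1640 ± 746.2, 2284 ± 1911 and 263.9 ± 234.3. The DLK1-DIO3 cluster had miR-127 at 178.3 ± 114.8, 218.4 ± 31.47, 178.6 ± 120.6 and 151.1 ± 106.1, miR-323 at 15.88 ± 3.986, 19.55 ± 5.627, 15.19 ± 7.842 and 9.359 ± 6.349, and miR-432-5p at 9.051 ± 4.801, 11.75 ± 3.209, 8.857 ± 4.637 and 5.404 ± 2.853. The milk list had miR-191 at 68410 ± 8219, 74480 ± 4587, 63230 ± 3361 and 55670 ± 5226, let-7a as above, and miR-22-3p at 13900 ± 4023, 8816 ± 1259, 9667 ± 2474 and 6199 ± 1264.

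The share of miR-194a in the sum of miR-194a and miR-194b-5p differed between groups, with 22.8% ± 4.54 in feeding piglets (SD, n = 3), 13.4% ± 2.13 after 1 day, 34.1% ± 4.03 after 3 days and 19.6% ± 2.74 after 7 days. An exact permutation test over the 15400 partitions of the libraries into 4 groups of 3 gave p = 0.000519.

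The share of miR-199a-3p in the sum of miR-199a-3p and miR-199b-3p fell into separate ranges that did not follow the groups. It was 11.9% in replicate 2 of the feeding group (95% Wilson interval 11.7% to 12.1%), 14.9% in replicate 3 of the group weaned for 1 day and 12.2% in replicate 2 of the group weaned for 7 days. It was 99.9% in replicate 1 of the group weaned for 7 days, and 77.8% to 82.6% in the other 8 libraries. The sum of both in CPM of known microRNAs was 7415 ± 1607 in feeding piglets (SD, n = 3), 8533 ± 1953 after 1 day, 8769 ± 864 after 3 days and 8373 ± 3102 after 7 days.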
